A study of Homo sapiens with 12 samples.

How the data were processed

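ChIP-seq peak lists of 8 libraries were used: H3K9me3 and H3K9me1, each from 2 control (0 hr) and 2 methionine-restricted (24 hr) samples of HCT116 cells. Files of the 4 input libraries were not used here. Groups and letters were taken from the sample labels. Per the submitters' processing notes, the tools were Bowtie2 2.1.0, SAMtools 1.5 and MACS2 2.1.1.20160309 with build hg19. Per the file headers, peaks were called per library with MACS2 in broad mode against the input of the same time and letter. Both marks of a time and letter thus share an input, and the larger library was scaled towards the smaller. Below, culture names the libraries of 1 time and letter, which the labels do not show to come from 1 culture. Per the file headers, H3K9me3 was called with q cutoffs of 0.05 (strong) and 0.1 (weak), and its fragment length was estimated at 299 to 302 bp. Per the file headers, H3K9me1 was called with p cutoffs of 0.0001 (strong) and 0.1 (weak) and at most 1 read per position, and its fragment length was estimated at 100 to 101 bp, close to the tag size of 101 bp. The 2 marks are therefore not comparable in number or length of regions. The deposited pileup is a signal, the read coverage at a region; the deposited p and q are −log10 values; and the deposited fold enrichment is a ratio of pileup to the local background, all averaged by the authors' caller over a broad region. These values were used to describe and filter peaks within a list. The weak H3K9me1 threshold admits many chance regions: 95.8% to 99.3% had a −log10 p below 2, and regions with −log10 p of at least 4 numbered 17, 0, 32 and 5. Within a mark the letter coincided with the sequencing lane, H3K9me3 A on lane 3 and B on lane 2, and H3K9me1 the reverse, per the file names recorded in the headers; ratios of A to A and B to B are thus within-lane values.

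All comparisons used chromosomes 1 to 22 and X, with each chromosome's length taken as the highest region end in any list (3035 Mb in all). Relative peak density is the covered share of a region or bin divided by the covered share of all chromosomes in that library, which removes the amount called; chromosomes that a list omits count as uncovered, which raises the H3K9me1 densities on the chromosomes a library lists, most in control B. For H3K9me1 windows the covered share of the listed or of the shared chromosomes was also used as the divisor, a choice made after the data were seen, and the text names it there. H3K9me3 peaks of the 4 libraries within 1 kb were merged; H3K9me1 regions were merged only where they overlapped. A region counted as present with an overlap of at least 1 bp. Centromere gaps were the region-free gaps at the known centromeres. Single values were compared by exact two-sided permutation tests over the 6 relabellings. Bins of 1 Mb with a peak in at least 2 libraries were tested with limma (lmFit, eBayes with trend and robust, Benjamini-Hochberg adjusted p under 0.05) on log2(relative density + 0.1), per mark; log2 differences understate changes of sparse bins. Because the H3K9me1 lists omit chromosomes, the H3K9me1 results were repeated on the 8 chromosomes present in all lists (1263 Mb), a choice made after the data were seen, as was the measure of evenness. The tests, the windows and the other alternatives of the comparisons were fixed before the data were examined; those chosen later are named with the closing observations. The alternatives tried were stricter thresholds, merging, other pseudocounts, scalings, filters and bin sizes, the letter as a replicate block, and leaving out each library.

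Bins and regions were named by a fixed rule: up to 10 bins per direction with the smallest adjusted p under 0.05, or, where fewer than 5 passed, the 5 with the largest log2 difference in which both restricted libraries lay on the same side of both controls and the mean density was at least 0.5; the 5 widest control-only, restricted-only and common regions; and all landmark windows, 9 of them set by hand in whole Mb. No gene annotation of hg19 was used, so gene-level tests, gene lists and set tests were not run and peaks are not assigned to genes, exons or introns; the windows stand in for gene groups. Gene counts per chromosome, taken from an annotation of GRCh38, served only for correlations across chromosomes, and no coordinate of it is given. Y, mitochondrial and unplaced sequences were left out of the comparisons.

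The interval code was checked against base-by-base counting on 300 random interval sets, of which 0 differed. The bin test was tested on simulated data with the means and spread of the real bins. On the shared chromosomes (1227 bins, 200 changed) log2 changes of 1 were recovered in 73.5% and of 2 in 95.5% of changed bins. False calls numbered 9 and 6, and 0 bins were called when nothing was changed. The simulated noise was independent between bins, so these numbers do not bound false calls from shifts that many bins of a library share. For H3K9me1 on all chromosomes (2734 bins) log2 changes of 4 were recovered in 0% and of 8 in 75.5%. The real fit there called a bin at a log2 difference of -1.44, so these shares do not set a limit of detection. The number of H3K9me1 regions did not follow the number of ChIP reads: restricted A had the most reads, 39452512, and the fewest regions, 387436. It ranked as the input reads did, from 23523460 in restricted A to 27843707 in restricted B, which had 760945 regions. On the shared chromosomes this order did not hold. There control B had 383762 regions and control A 330926, with 24434844 and 27721656 input reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.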

Results

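HCT116 is an established human colorectal carcinoma cell line. Its cells were profiled by ChIP-seq (chromatin immunoprecipitation with sequencing) for trimethylated and monomethylated lysine 9 of histone H3. H3K9me3 is a hallmark of constitutive heterochromatin, and H3K9me1 is a lower degree of methylation of the same residue. Control cells (0 hr) were compared with cells held for 24 hr in medium without methionine, the amino acid from which the methyl donor S-adenosylmethionine (SAM) is made. No library came from control cells at 24 hr, so restriction and time in culture cannot be told apart. Each mark had 2 control and 2 methionine-restricted libraries, lettered A and B, and 4 input libraries served as background. The question set by the design was where each degree of H3K9 methylation lay before and after depletion. Per the file headers, the H3K9me3 libraries held 35736289 (control A), 33503018 (control B), 33801853 (restricted A) and 35023269 (restricted B) reads. The H3K9me1 libraries held 30952210, 31683422, 39452512 and 35134998 reads in the same order, and the inputs 27721656, 24434844, 23523460 and 27843707. With 2 libraries against 2, the smallest two-sided p an exact permutation test can give is 0.333, so this test could not pass 0.05 for any single value. Nothing in the labels says that A and B came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

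Relative to length, H3K9me3 peaks were dense beside centromeres, near chromosome ends and on chromosome 19, in both conditions. Within 5 Mb of the centromere gaps the relative peak density, the covered share of a region divided by the covered share of the whole list, was 6.53 and 8.85 in control A and B and 5.42 and 8.05 in restricted A and B. In the first and last 2 Mb with peaks of the chromosomes it was 5.46, 5.24, 6.10 and 5.24 in that order. On the 8 chromosomes present in all H3K9me1 lists it was lower there, at 4.25, 2.49, 3.56 and 3.12. Chromosome 21 is not among these 8, and its first window may include sequence that is also counted beside the centromere gap. The zinc finger gene cluster at 19q13.4, whose KRAB zinc finger genes are known H3K9me3 targets, had densities of 8.16, 4.37, 6.48 and 7.56. The zinc finger cluster at 19p12 had 4.31, 2.20, 4.50 and 2.87. No H3K9me3 peak was listed in the olfactory receptor cluster at 11p15 in any of the 4 libraries, and the window around MYC at 8q24 held 0.302 kb in restricted A and none in the others. None of these windows separated the 2 conditions. The share of peaks within 5 Mb of a centromere gap was 32.6% (95% Wilson interval 30.2% to 35.1%) in control A, 44.0% (40.6% to 47.5%) in control B, 28.3% (26.3% to 30.4%) in restricted A and 40.8% (37.2% to 44.6%) in restricted B.

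The H3K9me3 regions found in every library lay in part beside the centromere gaps. Of 3228 merged regions, 150 were present in all 4 libraries, with a median width of 2154 bp, and 87 of these lay within 5 Mb of a gap. The widest was chr17:22244622-22261846 (hg19), with 14.9 kb under peaks in restricted A and more in each of the other libraries. The next were chrX:58565964-58581831, chr21:11059042-11073025, chr10:42383258-42397126 and chrX:61694248-61707970. The first of the X regions held 0.302 kb in restricted A against 13.7 kb in control B and 12.1 kb in restricted B. These recurrent regions had a high read pileup and a modest fold over input, both as the authors' peak caller gave them. In control A the median pileup was 86.7 at peaks over recurrent regions and 18.9 elsewhere, while the median fold enrichment was 2.05 and 3.08. The background implied by pileup and fold near the gaps was 36.5 to 41.4 times the level expected from input depth, so these sites were covered deeply in the input as well.

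The total amount of H3K9me3 called did not separate the conditions, but the peaks with the highest −log10 q covered less sequence in both restricted libraries. The lists held 1372 and 797 peaks in the control libraries (1084.5 ± 407, SD, n = 2) and 1880 and 674 in the restricted libraries (1277 ± 853, SD, n = 2; exact permutation p = 1, two-sided). Covered length was 1.45 and 0.944 Mb against 1.77 and 0.711 Mb (exact permutation p = 1). Within the A libraries, which shared a sequencing lane, restricted over control was 1.37 for peaks and 1.22 for length; within the B libraries it was 0.846 and 0.753. Peaks with −log10 q of at least 5 numbered 158, 135, 176 and 117, and covered 0.367 and 0.328 Mb in the control libraries but 0.266 and 0.243 Mb in the restricted libraries (exact permutation p = 0.333, the smallest possible). Strength by fold gave another picture: peaks with a fold enrichment of at least 4 numbered 278 in restricted A against 45, 30 and 29 in control A, control B and restricted B. They covered 0.0238 and 0.0149 Mb in the control libraries and 0.196 and 0.0143 Mb in the restricted libraries (exact permutation p = 1).

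**Figure D1:**
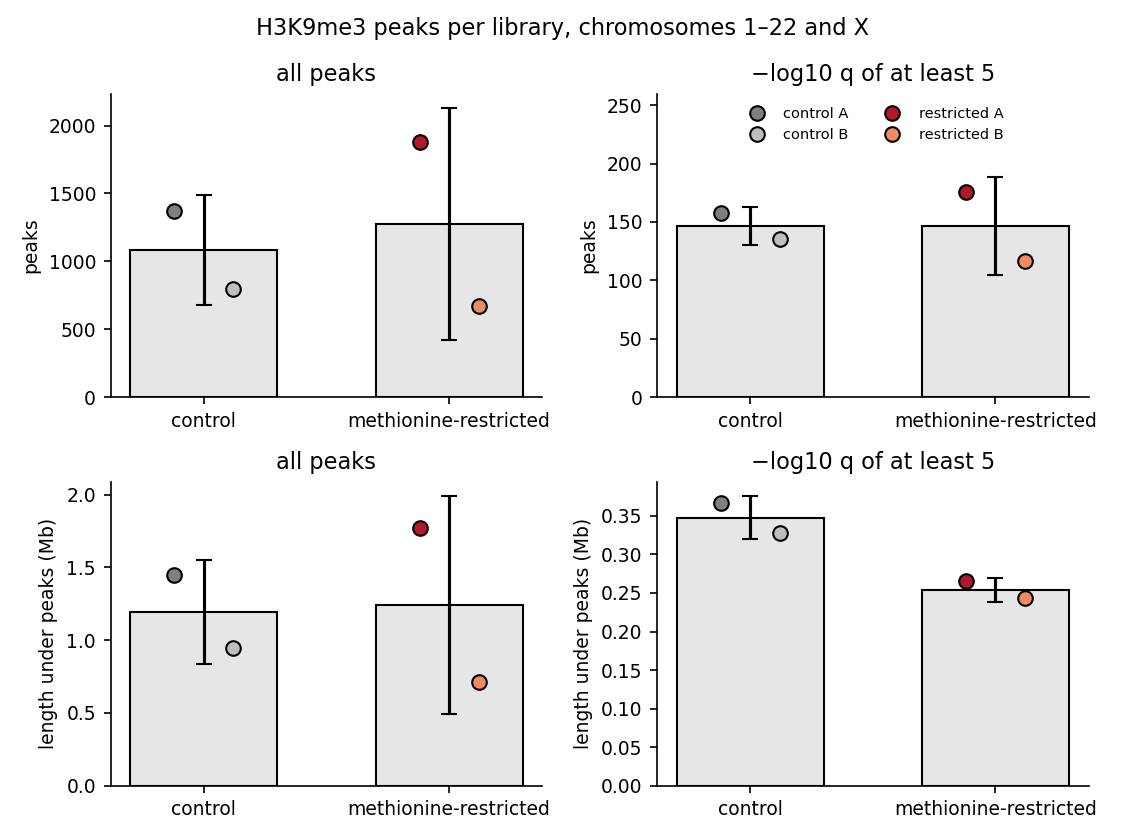
Number of H3K9me3 peaks (top) and length under them in Mb (bottom) per library, for all peaks (left) and for peaks with −log10 q of at least 5 (right); bars are means of 2 libraries, error bars the SD, points the libraries. The restricted libraries lie on both sides of the controls at 1880 and 674 peaks, while the length under peaks with −log10 q of at least 5 is 0.367 and 0.328 Mb in control and 0.266 and 0.243 Mb in restricted libraries.

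A small set of H3K9me3 regions followed the condition in both replicates. In all, 69 regions were present in both control libraries and neither restricted library, and 79 in both restricted libraries and neither control library. The widest control-only regions were chr21:9664707-9668901, chr16:33308947-33312865, chr7:16436539-16439472, chr21:10084993-10087779 and chr14:20070831-20073605. The widest restricted-only regions were chr22:20710061-20715215, chr19:19820564-19824440, chr7:6730347-6733759, chr21:10137890-10141229 and chr9:68454000-68456806. Of these 10 regions, only those on chromosome 7 lay more than 5 Mb from a centromere gap. The region on chromosome 19 reached a fold enrichment of 4.10 in restricted A and 4.45 in restricted B, and that at chr7:6730347-6733759 reached 4.17 and 3.76. For the split by letter the numbers were 167 in both A libraries alone and 23 in both B libraries alone, and the crossed split gave 48 and 64. The product of each list's share of the merged regions gives 110 control-only and 165 restricted-only regions. Every merged region is in at least 1 list by construction, so this product is not a chance level for these counts. With −log10 q of at least 5, 18 regions were control-only and 5 restricted-only, against 5 and 4 by letter and 4 and 5 crossed. The same product there gives 16.9 and 16 by condition. With equal numbers of peaks per library, the highest by q, the numbers were 54 and 39 by condition. They were 37 and 46 by letter and 42 and 21 crossed, and the product gives 96.4 each by condition. The 4 libraries allow 3 such splits, too few for a test. The base-pair Jaccard index was 28% for the control libraries, 15.5% for the restricted libraries and 18.8% to 23.5% for pairs across conditions. For peaks with −log10 q of at least 5 it was 72.6% for the control libraries, 36.1% for the restricted libraries and 42.4% to 50.7% across conditions.

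By chromosome, H3K9me3 was lower on 4 and higher on 7 chromosomes in both restricted libraries than in both controls. Chromosome 4 had relative densities of 1.26 and 1.29 in control and 1.02 and 0.555 in restricted libraries, and chromosome 2 had 0.973 and 0.980 against 0.796 and 0.702. Chromosomes 5 and 10 were the others on the lower side. Chromosome 22 had 0.898 and 1.01 against 1.41 and 1.40, and chromosome 20 had 0.450 and 0.615 against 0.819 and 0.682. Chromosomes 7, 9, 11, 12 and 19 were the others on the higher side. Such separation in 11 of 23 chromosomes (47.8%) stands beside the 33.3% that chance gives with 2 against 2, and each has an exact permutation p of 0.333. Chromosome X had 0.711 and 1.15 in control libraries and 0.275 and 1.40 in restricted libraries.

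**Figure D2:**
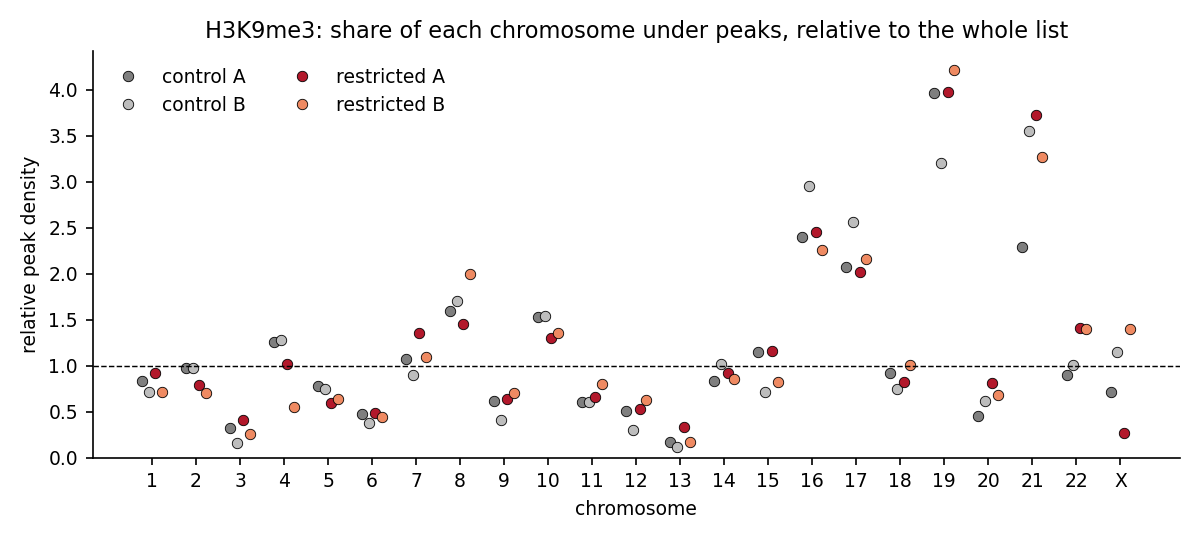
Relative H3K9me3 peak density (share of a chromosome under peaks divided by the share for the whole list, no unit) for chromosomes 1 to 22 and X; each point is a library and the dashed line marks a density of 1. Chromosome 19 lies highest in control A, restricted A and restricted B, at 3.96, 3.98 and 4.22, and chromosome 21 in control B, at 3.55.

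No 1 Mb bin passed the test for H3K9me3. Of 678 bins with a peak in at least 2 libraries, limma called 0 at an adjusted p under 0.05 (smallest 0.492), and 62 had an unadjusted p under 0.05. The same fit with the libraries split by letter called 71. The bins with the largest differences are given as values. Higher in both restricted libraries were chr7:6000001-7000000, with a relative density of 0 in both controls against 5.89 and 9.45, chr19:49000001-50000000 with 6.26 and 3.86, chr13:57000001-58000000 with 5.38 and 3.20, chr17:3000001-4000000 with 3.62 and 4.59, and chr19:35000001-36000000 with 3.91 and 3.62, all listed at 0 in both controls. At 0 in both restricted libraries were the end of chromosome 21 (chr21:48000001-48119822), with 26.3 and 11.4 in the controls, the end of chromosome 16 (chr16:90000001-90294695) with 17.8 and 14.8, chr9:130000001-131000000 with 5.34 and 6.08, chr5:178000001-179000000 with 7.86 and 3.6, and chr14:31000001-32000000 with 4.59 and 5.77. The end bins of chromosomes 21 and 16 are cut off by the chromosome end and are much shorter than 1 Mb. A short length under peaks therefore gives a high density there. Few kb can also make up the density of a full bin. The bin chr7:6000001-7000000 holds the restricted-only region chr7:6730347-6733759, with 1.56 and 2.21 kb under peaks in restricted A and B. With 5 Mb bins, 1 bin was called, lower in the restricted libraries. On simulated data with the spread of these libraries, log2 changes of 4 were recovered in 0% of bins and of 8 in 43.8%. These shares do not set a limit of detection. For H3K9me1 on all chromosomes the same simulation also recovered 0% at 4. The real fit there called chr16:81000001-82000000 at a log2 difference of -1.44.

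H3K9me1 was listed as short, weak regions spread over the genome, covering 308 and 226 Mb in control A and B and 149 and 358 Mb in restricted A and B. The lists held 661085, 454516, 387436 and 760945 regions, with a median fold enrichment of 1.98, 1.82, 1.85 and 1.83. Between the conditions, neither the count (557800 ± 146066 against 574190 ± 264111, SD, n = 2; exact permutation p = 1) nor the covered length (267 ± 58.1 against 253 ± 148 Mb, SD, n = 2; exact permutation p = 1) was separated. Within A libraries restricted over control was 0.586 for the count, and within B libraries 1.67. The lists lacked whole chromosomes: 20 of 23 were listed in control A, 10 in control B, 21 in restricted A and 19 in restricted B, and X in none. Chromosomes 1, 2, 6, 7, 10, 12, 16 and 17 were in all 4 lists, and on these 8 the regions numbered 330926, 383762, 186609 and 394290 and covered 157, 191, 72.2 and 187 Mb. Of the 5 widest control-only H3K9me1 regions, all lay on chromosome 3, which restricted B did not list, the widest at chr3:126626016-126634598. The others began at 9158312, 134470944, 124767168 and 12214289. The 5 widest restricted-only regions lay on chromosomes 19, 14, 13 and 9, which control B did not list, the widest at chr19:4766955-4772694. On the 8 shared chromosomes 44396 regions were control-only and 19718 restricted-only, against 11015 and 48481 for the split by letter and 35901 and 15555 for the crossed split. The product of each list's share of the merged regions gives 57628 control-only and 27208 restricted-only regions, again not a chance level. The Jaccard index there was 14.5% for the control libraries and 7.78% for the restricted libraries, and 6.85% to 13.2% across conditions.

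**Figure D3:**
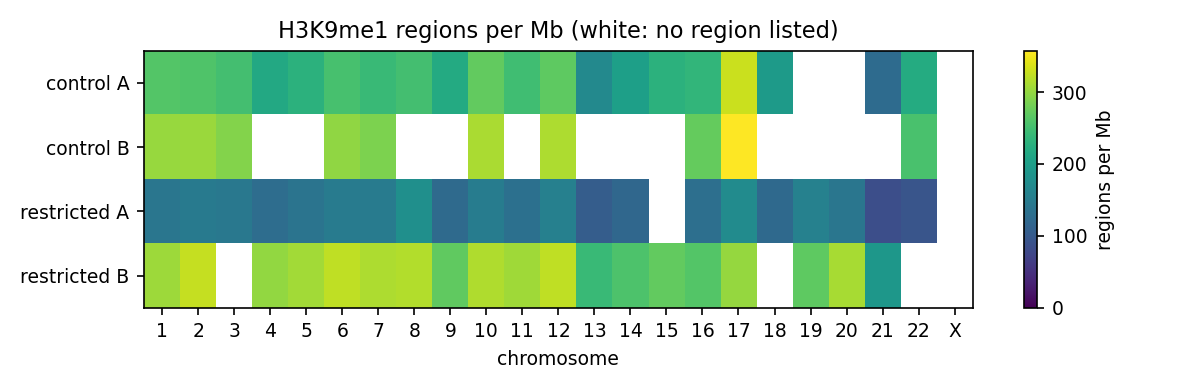
H3K9me1 regions per Mb (colour) for chromosomes 1 to 22 and X in each of the 4 libraries; white means that no region was listed. Control B lists 10 chromosomes and the other libraries 19 to 21.

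On the shared chromosomes, the listed H3K9me1 regions were more evenly spread in the restricted libraries. Relative to the covered share of each list, Mb-sized stretches poor in H3K9me1 in the control libraries held more, and rich stretches less. Across 1227 bins of 1 Mb, the SD of log2 relative density was 0.979 and 0.850 in control libraries and 0.585 and 0.479 in restricted libraries (0.915 ± 0.0908 against 0.532 ± 0.0748, SD, n = 2; exact permutation p = 0.333, the smallest possible). The 90th percentile over the 10th was 6.27 and 5.13 against 3.11 and 2.28. In the 122 bins lowest in control A, the mean relative density was 0.173 in control B, 0.499 in restricted A and 0.446 in restricted B. In the 123 bins highest in control A it was 1.62, 1.27 and 1.17. Restricted B and control B covered nearly the same length, 187 and 191 Mb. This measure was chosen after the data were seen. It compares shares within each list, and without scaling the median log2 difference over these bins was -0.45. How far chance regions, which the weak threshold admits, add to the evenness of a list was not tested. Over the same bins, log2 relative density correlated at 0.978 (Pearson) between the controls and at 0.769 between the restricted libraries. Across conditions r was 0.762 to 0.895, a range that holds the value of the restricted pair. The restricted libraries thus did not share a profile of their own more closely than they resembled the controls.

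**Figure D4:**
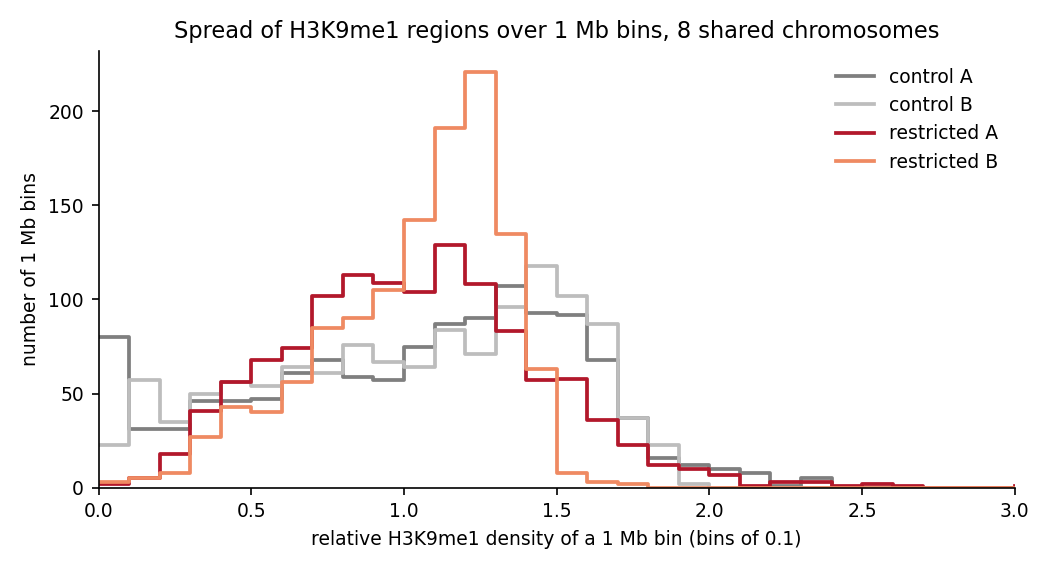
Distribution of the relative H3K9me1 density (no unit) over 1227 bins of 1 Mb on the 8 shared chromosomes, as the number of bins per step of 0.1 in density; each line is a library. The 90th percentile is 6.27 and 5.13 times the 10th in the control libraries and 3.11 and 2.28 times in the restricted libraries.

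Megabase stretches on chromosomes 7, 10, 1, 2, 12 and 16 held relatively more H3K9me1 in the restricted libraries, and stretches on chromosomes 1, 16 and 17 relatively less. On the shared chromosomes limma called 162 of 1227 bins, 123 higher and 39 lower in the restricted libraries, with a median log2 difference over all bins of 0.08. The 10 higher bins with the smallest adjusted p (0.0206 for each) included both bins from chr7:62000001 to 64000000 and chr10:37000001-38000000, all within 5 Mb of a centromere gap. At chr7:63000001-64000000 the relative density was 0.0647 and 0.150 in control and 0.857 and 0.575 in restricted libraries (log2 difference 1.99, SE 0.30, adjusted p = 0.0206). The others were chr10:10000001-11000000 (log2 difference 1.91), chr1:240000001-241000000 (1.87), chr16:64000001-65000000 (1.78), chr7:70000001-71000000 (1.74), both bins from chr2:4000001 to 6000000 (1.59 and 1.62) and chr12:126000001-127000000 (1.59). The 10 lower bins all lay on chromosomes 1, 16 and 17. At chr16:81000001-82000000 the density was 2.12 and 1.68 in control and 0.848 and 0.855 in restricted libraries (log2 difference -1.06, SE 0.15, adjusted p = 0.0206). The others on chromosome 16 began at 11000001, 27000001 and 84000001, with log2 differences of -0.63, -0.64 and -1.20. Those on chromosome 17 began at 17000001, 43000001 and 75000001, with -0.77, -0.94 and -0.84. Those on chromosome 1 began at 17000001, 22000001 and 23000001, with -0.91, -0.63 and -0.62. The calls depended on the scaling: quantile normalization, which gives every library the same distribution, gave 0 calls, as did no scaling, which moved the median difference to -0.45, and no filter on bins. These 3 fits had 162, 3 and 408 bins with an unadjusted p under 0.05, and 641 and 402 bins were called without restricted A and restricted B. The excess of higher bins was lost without restricted B, where 193 were higher and 209 lower, while without restricted A 396 were higher and 245 lower. With the letter as a block 191 were higher and 88 lower, and with the crossed pairing, chosen after the data were seen, 172 of 273 were higher.

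The fit planned over chromosomes 1 to 22 and X called 263 of 2734 H3K9me1 bins, 242 higher and 21 lower, but the 10 higher bins with the smallest adjusted p all lay on chromosomes 19 and 20, which neither control library listed. Their control densities of 0 therefore come from unlisted chromosomes. Because control B listed 10 of 23 chromosomes and its covered share was taken over all of them, its densities on listed chromosomes are raised in this fit: chr16:81000001-82000000 had 3.42 in control B here and 1.68 on the shared chromosomes. Among the higher bins the first, chr19:27000001-28000000, had 0.195 and 0.137 in the restricted libraries (limma adjusted p = 1e-05). The others were 4 bins on chromosome 19, at 20, 24, 28 and 31 Mb, and 5 on chromosome 20, at 7, 12, 15, 26 and 59 Mb. The 10 lower bins included chr1:18000001-19000000, with 2.01 and 3.33 in control and 0.325 and 1.45 in restricted libraries, chr2:121000001-122000000, chr10:80000001-81000000, 3 bins on each of chromosomes 16 and 17 and 1 on chromosome 3, which restricted B did not list and where it is at 0. With the letter as a block 117 bins were higher and 41 lower. Without control A 1329 bins were called, 1004 higher and 325 lower, without restricted A 1, and without control B or restricted B 0.

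H3K9me1 regions lay over H3K9me3 regions several times more densely in the restricted libraries. Over 363 regions (924 kb) present in both control H3K9me3 libraries, the relative H3K9me1 density was 0.569 and 0.453 in the control libraries, below the genome average, and 2.96 and 1.46 in the restricted libraries, above it (0.511 ± 0.0818 against 2.21 ± 1.06, SD, n = 2; exact permutation p = 0.333, the smallest possible). The ratio of the means was 4.33. The position relative to the genome average depended on the threshold: with only H3K9me1 regions of −log10 p of at least 2, chosen after the data were seen, the densities were 9.49 and 16.9 in control and 67.0 and 40.4 in restricted libraries, all above it. Such regions covered 3.0% and 0.650% of the H3K9me3 regions in control and 1.65% and 2.75% in restricted libraries, which did not separate the conditions. Within the A libraries the ratio with all regions was 5.21 and within the B libraries 3.23. On the 8 chromosomes listed in all libraries the ratio was 3.51. Away from the centromere gaps, over 174 regions, the densities were 0.215 and 0.363 in control and 5.26 and 1.77 in restricted libraries, a ratio of 12.2. Near the gaps the ratio was 2.26. Over the 69 control-only H3K9me3 regions the ratio was 5.26, over the 79 restricted-only regions 15.8 and over the 150 regions in all 4 libraries 3.15. These ratios differed between the A and the B libraries. They were 11.2 and 2.80 over control-only, 25.4 and 7.26 over restricted-only and 3.62 and 2.49 over the common regions. Restricted A carried the larger difference, and without it the log2 ratio was 1.52 in place of 2.12. Over the 150 regions, the listed H3K9me1 regions had a lower median pileup in the restricted libraries, 4.99 and 19.3 against 50.8 and 33.6 in control, with a median fold of 1.82 and 1.53 against 1.39 and 1.43. They numbered 78 and 55 in control and 130 and 185 in restricted libraries. Counted by peak on the shared chromosomes, H3K9me1 regions touched 107 (18.5%, Wilson interval 15.6% to 21.9%) and 142 (24.6%, 21.2% to 28.2%) of the 578 H3K9me3 peaks of control A in the control libraries. In the restricted libraries they touched 270 (46.7%, 42.7% to 50.8%) and 314 (54.3%, 50.2% to 58.3%) of them. These intervals cover counting error only.

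**Figure D5:**
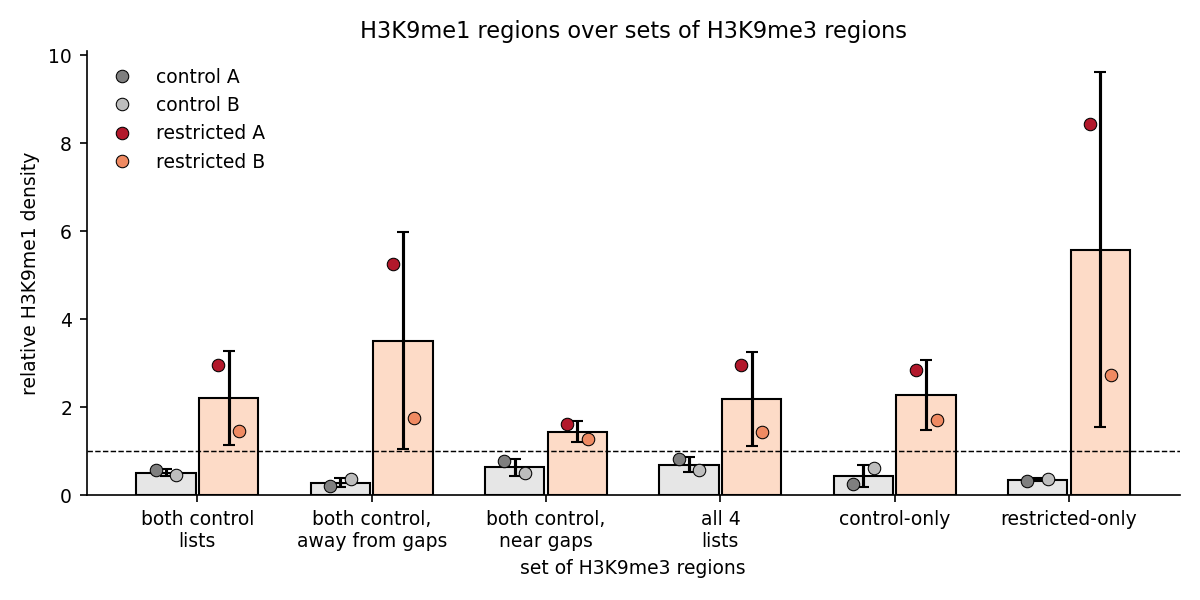
Relative H3K9me1 density (covered share of the H3K9me3 regions divided by the genome-wide covered share, no unit) over 6 sets of H3K9me3 regions; bars are means of 2 libraries, error bars the SD, points the libraries, and the dashed line marks the genome average. Over the regions of both control lists the control libraries lie at 0.569 and 0.453 and the restricted libraries at 2.96 and 1.46.

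Near the centromere gaps the relative H3K9me1 density, divided by the covered share of the whole genome, was 0.790 and 0.770 in control and 1.01 and 0.906 in restricted libraries (exact permutation p = 0.333). On the 8 shared chromosomes alone it was 0.857 and 0.886 against 1.0 and 0.920 (exact permutation p = 0.333). Near chromosome ends it was 1.07 and 0.940 against 1.15 and 1.03, with no separation of the conditions. The histone gene cluster at 6p22 had 1.19 and 2.33 in control and 1.95 and 1.60 in restricted libraries, which did not separate the conditions (exact permutation p = 1). The MHC at 6p21, which holds the antigen-presentation genes, had 1.65 and 2.76 against 1.58 and 1.55 (exact permutation p = 0.333). Both values on chromosome 6 depended on the divisor, since control B listed 10 chromosomes. Divided by the covered share of the shared chromosomes, a choice made after the data were seen, the histone cluster had 0.974 and 1.15 against 1.67 and 1.27, and the MHC 1.35 and 1.36 against 1.35 and 1.24 (exact permutation p = 0.333 for each). Over the chromosomes each library listed, also chosen after the data were seen, the histone cluster had 1.08 and 1.16 against 1.79 and 1.34 (exact permutation p = 0.333), while the MHC had 1.5 and 1.37 against 1.44 and 1.30, with no separation (exact permutation p = 0.667). For windows on chromosomes that a control library did not list, no comparison was made, and their values were divided by the covered share of the chromosomes each library listed. In the restricted libraries the zinc finger cluster at 19q13.4 had 1.68 and 1.01 and that at 19p12 0.802 and 0.567. The protocadherin cluster at 5q31 had 1.61 and 0.971, with 0.726 in control A. The olfactory receptor cluster at 11p15 had 1.46 in control A and 1.23 and 1.34 in restricted libraries, that at 11q11 had 0.252 against 0.427 and 0.582, and the MYC window had 1.28 against 1.38 and 1.09. The imprinted region 15q11-q13 had 0.306 in control A and 0.641 in restricted B. H3K9me3 in the same windows rested on few peaks. It was 1.53 and 3.89 against 1.29 and 0 at the protocadherins, 0 in both controls and 1.83 and 0 in restricted libraries at the histone genes, and 1.5 and 0.481 against 0.376 and 0.645 at 11q11. At the MHC it was 0 and 0.586 against 0.446 and 1.52, and at 15q11-q13 4.02 and 0 against 1.96 and 2.37. The 5 widest H3K9me1 regions present in all 4 lists were chr1:229288477-229297252, chr1:37566404-37575069, chr6:34548942-34557510, chr1:153404176-153412582 and chr12:100580184-100588303.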

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

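Some tests were chosen only after the result was seen. They were those of the missing chromosomes and of the longer A lists, and the centromere comparison on shared chromosomes. For the H3K9me1 density over H3K9me3 regions, so were those of evenness, shared input, input coverage and index sharing without the own culture. The restrictions of that density to shared chromosomes and to regions away from centromere gaps were also chosen after the data were seen. The test of index sharing with every library was written before its result was seen. Some sequences outside the main comparisons carried at least 5 kb of signal in a restricted library and none in the controls. H3K9me3 peaks covered 32.7 kb of the unplaced chromosome 9 sequence gl000199 in restricted B (23 peaks) and 4.77 kb in restricted A. They covered 6.65 kb of the mitochondrial sequence, which carries no histones, in restricted B. H3K9me1 regions covered 12 kb of the unplaced sequence gl000212 and 59.3 kb of Y in restricted A. Near the centromere gaps of the 8 chromosomes in all H3K9me1 lists, restricted over control was above 1 for H3K9me1 (1.17 in A and 1.04 in B) and below 1 for H3K9me3 (0.779 and 0.953); the log2 ratios of the group means differed by 0.33, and this difference was not tested.

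The first pattern is the higher density of H3K9me1 over H3K9me3 regions in the restricted libraries. Methionine restriction is the explanation the design names, untested against those that stay open. All controls were taken at 0 hr and all restricted libraries at 24 hr, so restriction cannot be told apart from time in culture. The make-up of the lists is argued against as the whole cause: the ratio was 3.51 on the chromosomes present in all lists and 12.2 away from the centromere gaps, with both restricted libraries above both controls, and on the listed as on the shared chromosomes both exceeded the level of an even spread over 10 kb windows with any H3K9me1 region by at least 2.53 bootstrap SE, restricted B by the least (1.42 against 1.05). Over regions found in 1 H3K9me3 library only, restricted A reached 9.84 for its own culture and 2.07 to 3.03 for the others. Restricted B had 3.13 against 1.49 to 2.34 and control B 0.892 against 0.556 to 0.632, while control A had 0.598 both for its own and for those of restricted A. The shared input and a signal of the culture itself were thus not separated. Over regions of both control lists, called against other inputs, the lower restricted density was still 2.57 times the higher control density. Lower input coverage in the restricted cultures stays open away from the gaps, where the implied background was 0.984 of control in the B pair and 0.794 in the A pair. Near the gaps it is argued against by the H3K9me3 lists, where the background was 1.08 (SE 0.0131) and 1.11 (SE 0.0291) of control in the same order. H3K9me1 over the same 87 regions was 2.12 and 1.44 times as dense. At H3K9me1 regions there, listed in both libraries of a pair, the background was 0.955 (SE 0.0391) of control in the B pair and 1.09 (SE 0.0866) in the A pair. These rest on 17 and 19 of the regions. Each restricted H3K9me1 library, and no control one, shared part of its index with an H3K9me3 library of its lane, and the test of such stray reads written in advance found another H3K9me3 library denser than the partner in both cases, by 7.77 (SE 0.360) in restricted A and 0.788 (SE 0.243) in restricted B; that bound was wrong, because the denser library was each time the own culture's, called against the same input, and an excess there leaves reads of the partner open, so the test was repeated without it after this was seen. Restricted A was then still denser over regions of control A than over those of its partner, control B, by 0.962 (SE 0.331). Reads of that partner stay open all the same, because the 2 sets of regions differed also in the control H3K9me1 libraries, which shared no index part. There the densities over regions of control A and of control B were 0.598 and 0.229 in control A, and 0.556 and 0.892 in control B. Restricted B was denser over regions of its partner, restricted A (other minus partner -0.714, SE 0.132). There stray reads and the condition cannot be told apart, since the partner is itself a restricted library.

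The second pattern is the absence of whole chromosomes from the H3K9me1 lists, in 22 combinations of library and chromosome. For 18 combinations another H3K9me1 list held the chromosome, with at least 0.523 of that list's median regions per Mb. The H3K9me3 list of the same culture held at least 7 peaks there. These chromosomes were thus not poor in regions in the other lists. Neither value measures H3K9me1 reads in the library that lacks the chromosome, so too few reads stay open. The same holds for the 4 combinations of X, which no H3K9me1 list held. There the H3K9me3 lists of the same culture held at least 10 peaks. A candidate explanation is that the caller lists weak regions only on sequences where it found a strong one. The 2 small sequences listed, gl000212 and Y in restricted A, each held regions with −log10 p of at least 3, which chance would give with a probability of 0.000476. No biological explanation was tested.

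The third pattern is that both A lists of H3K9me3 were longer than both B lists, the shortest A list holding 1.72 times the peaks of the longest B list. Depth argues against itself as the cause, since the shallower A library had 0.965 times the reads of the deeper B library, and the inputs interleaved, with a ratio of 0.845 in the same sense. The sequencing lane and the letter cannot be told apart, because each letter was on its own lane, and no biological explanation was tested.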

How the results depend on the processing

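Some alternatives were chosen after the data were seen. They covered the chromosomes shared by all H3K9me1 lists, regions away from centromere gaps, regions in both restricted H3K9me3 libraries, and −log10 p of at least 2. Also chosen then were all those of the shared-chromosome bins and of evenness, the other divisors of H3K9me1 windows and the crossed pairing. The log2 ratio of H3K9me1 density over H3K9me3 regions stayed above 0 in its alternatives, between 1.52 and 3.6, and the replicate block gave 2.04. This range leaves out the restricted-only regions and those near the gaps, with ratios of 15.8 and 2.26 before taking logs. It also leaves out −log10 p of at least 2 without division by the covered share. There the regions covered 3.0% and 0.650% in control and 1.65% and 2.75% in restricted libraries, with no separation. Evenness kept its direction throughout (-0.51 to -0.20, -0.38 in the replicate block). The exact permutation test used for these cannot give a p under 0.333 with 2 libraries against 2. Signs of the amounts were not stable, and the cause was not tested. For H3K9me3 the log2 ratio of peak count was 0.24, 0.00 with −log10 q of at least 5, 2.03 with fold of at least 4, and -0.69 to 0.79 leaving out a library. That of covered length was 0.05, -0.45 with −log10 q of at least 5, 2.44 with fold of at least 4, -0.0600 in the replicate block, and -0.75 to 0.57 leaving out a library. For H3K9me1 the count ratio of 0.04 became -0.30 on shared chromosomes, -1.81 with −log10 p of at least 2, -0.0137 in the replicate block, and -0.53 to 0.45 leaving out a library. Its length ratio of -0.08 became 3.65 with fold of at least 4, which left at most 8 regions in a library, and -0.85 to 0.42 leaving out a library. H3K9me3 restricted-only regions fell from 79 to 39 with equal numbers of peaks and to 5 with −log10 q of at least 5, where control-only regions numbered 18. H3K9me1 restricted-only regions numbered 55426, and 19718 on shared chromosomes; requiring at least 0.5 of a region to lie under peaks left 40476 control-only and 29758 restricted-only.

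H3K9me3 bins went from 0 calls to 1 with 5 Mb bins and stayed at 0 in the replicate block. H3K9me1 bins on all chromosomes gave 263 calls, 162 on shared chromosomes, 158 in the replicate block, 0 without scaling, with quantile normalization, without trend and with 0.1 Mb bins, and 0 to 1329 leaving out a library. On shared chromosomes the 162 calls became 0 without scaling, with quantile normalization or without the filter, 279 in the replicate block and 116 to 641 leaving out a library; the median log2 difference was 0.08, and -0.45 without scaling. The letter does not establish a pairing: deviations of same-lettered libraries correlated at 0.109 for H3K9me3 bins, -0.230 for H3K9me1 bins and -0.105 on shared chromosomes. The crossed pairing gave 246 calls for H3K9me1 on all chromosomes and 273 on shared ones. Leaving out a library leaves 1 in its group, which limma then assumes to vary like the other group. Filters on q could not be run for H3K9me1, where they left at most 3 regions in a list; the H3K9me3 bins could not be fitted without a filter; gene alternatives were not run.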

Other observations

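Of the unplaced sequences, those with H3K9me3 peaks in all 4 libraries are given here, and others were listed in fewer libraries. Both restricted libraries had less length under peaks than both controls on gl000225 (82.2 and 77.7 kb in control against 16 and 56.0 kb), gl000216 (24.3 and 25.2 against 13.6 and 12.5 kb), gl000214 (23.3 and 26.3 against 15.3 and 12.9 kb), gl000224 (20.1 and 17.8 against 13.5 and 11.5 kb) and gl000220, which holds ribosomal DNA (37.1 and 37.1 against 36.8 and 22.7 kb). On gl000226 peaks covered 15 kb in each library. The conditions overlapped on gl000193 (15.4 and 17.7 against 15.8 and 18.2 kb), gl000228 (11 and 3.63 against 8.62 and 3.75 kb), gl000208 (4.60 and 5.58 against 3.39 and 6.45 kb), gl000212 (2.06 and 3.82 against 7.31 and 3.72 kb), gl000221 (4.72 and 2.38 against 3.90 and 0.384 kb) and gl000235 (2.15 and 3.30 against 1.2 and 2.17 kb). These sequences were chosen after their values were seen, and covered length moves with the amount called.

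The correlation tests here were planned before their results were seen. H3K9me3 density differed between chromosomes, and a hypothesis was that it follows the number of zinc finger genes per Mb, counted on GRCh38. Over 23 chromosomes Pearson's r was 0.735, 0.470, 0.625 and 0.681 in control A, control B, restricted A and restricted B (permutation p = 0.00187, 0.049, 0.00493 and 0.00498; adjusted p at most 0.049 over 8 correlations), and Spearman's rho was 0.313, 0.244, 0.398 and 0.415 (permutation p = 0.147, 0.259, 0.0614 and 0.0499; adjusted p at least 0.235). Without chromosomes 16 and 19, which lie farthest from the median, r was between -0.063 and 0.085, so the relation rests on those 2. For other protein-coding genes r was 0.515 to 0.679 (permutation p at most 0.0164, adjusted at most 0.0187) with rho from 0.102 to 0.350 (permutation p at least 0.105), and without chromosomes 17 and 19 r was at least 0.053 and at most 0.119. Chromosomes are not independent replicates, and neither gene count accounted for the differences among the remaining chromosomes.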
